A study of Mus musculus with 29 samples.

How the data were processed

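Total RNA from cultured mouse cells was labelled with Cy3 and hybridised to single-colour Agilent expression arrays, 29 arrays in 9 groups. Per the labels, ESC are embryonic stem cells of the double reporter line HRHnG kept in the inhibitor pair called 2i with LIF, Diff are the same cells after 7 to 8 days with Activin, CHIRON and LIF, and Mid and Late are endoderm cultures (nEnd) passaged from Diff, at passage 7 to 10 and passage 14 to 15. XEN are extraembryonic endoderm cells of their own line, and EpiSC are epiblast stem cells. ADE are EpiSC after 4 days of differentiation to anterior definitive endoderm. The labels spell the line of EpiSC and ADE as HRHNG, and it was taken to be HRHnG. The 2iL and NACL groups are stem cells of the lines HVMC, E14 and E14-NanogGFP kept for at least 3 passages in 2i with LIF or in N2B27 medium with Activin, CHIRON and LIF. ADE and NACL hold 4 arrays each and the other groups 3. Per the design text, the nEnd replicates are separate differentiations; what separates the replicates of the other groups is not stated, so every p-value measures only the spread between these samples.

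Per the file headers, the deposited scanner files hold the intensity of each spot as read by Agilent Feature Extraction, with a background-corrected signal, the raw median signal, the local background and marks for spots well above background, saturated or irregular. The version is 9.1 in the submitters' processing notes, while the file headers give 11.0.1.1 for ESC, Diff, Mid, Late and XEN (the first array set, slides 1 to 4, read on 2 scan days) and 12.0.1.1 for 2iL, EpiSC, ADE and NACL (the second set, slides 5 and 6, read on 1 day). The log2 values used here were calculated from that signal, which, per the file headers, the software had background-corrected before deposit. Groups of different sets share no slide, scan day or software version. The authors also deposited a series matrix with unstated scale. Its columns had medians from 5.94 to 5.949 and correlated with the log2 scanner signal at 0.909 to 0.937, so its values were read as log2, equalised between arrays and not centred per gene; its log base and its background step are not stated, and it served as an alternative only.

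Spots marked as irregular were left out, from 132 to 243 of 59305 per array, and spots of the same probe were averaged. The main values are log2 of the background-corrected signal minus the 75th percentile of each array over all non-control probes. That percentile was 152 to 367 intensity units, 49.2% to 79.7% of probes were well above background, and 0 probes were saturated. The number of arrays limits the precision. Of 55681 probes, 27636 received a gene symbol through their accession (annotation of assembly GRCm38.p6, used for names only, since the headers name build mm9), giving 20956 symbols. Of these, 5552 had several probes, and the probe with the highest mean over all arrays stood for the gene; of 4223 genes with another probe tested, that probe was called in the opposite direction for 25 (Diff minus ESC), 13 (Mid minus Diff), 0 (Late minus Mid and NACL minus 2iL), 57 (nEnd minus XEN), 26 (ADE minus EpiSC) and 63 (nEnd minus ADE). The 33 probes with conflicting symbols and the 28045 without a symbol were kept apart. Genes were tested if their probe was well above background on all arrays of at least 1 group, which left 16332. The 717 probes whose accession differed between both sets of files were named from the second set, or from the first where the second gave no symbol. In all, 135 missing values remained.

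One limma model of 9 group means, fitted to all arrays with a shared estimate of the spread, gave each difference on the log2 scale with its standard error (lmFit and eBayes, limma 3.58.1 in R 4.3.3 with the package data.table, version 1.17.8). Files were read with Python 3.11.15 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. There were 7 main comparisons, 3 secondary ones and 2 differences of differences; nEnd is the mean of Mid and Late with equal weight. A probe well above background on no array of a side has only a bound there; where only some arrays of a side are well above background, the fitted difference is given with their number and is less certain. The fold is then the mean of the bright side over the mean of the dim side, with each dim array taken at the higher of its own value and the lowest signal among probes well above background, and it is written as at least that fold. For 29 gene lists, camera compared each list with all other genes at a preset correlation of 0.01 and again with an estimated correlation, with missing values replaced by the group mean, adjusted over the lists of a comparison. Distance to XEN is the root mean square log2 difference of an array from the XEN mean over all genes tested, compared by exact two-sided permutation tests. For a XEN array the mean of the other XEN arrays was used.

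The groups, model, threshold, gene lists and the rule for naming genes were fixed before the data were examined. The rule names, per main comparison, the 8 largest changes in each direction among genes called with a symbol, measured on all arrays and without overlap of arrays; the 4 largest bounds in each direction; and up to 4 called members of each list with the largest changes. Secondary comparisons and differences of differences name 4 in each direction. Data were simulated from each gene's mean over all arrays and its spread, with 200 of 16332 genes changed and no slide effects. Every real comparison called a larger proportion of genes, and recovery depends on that proportion. The recovery therefore does not give the sensitivity of the real comparisons. On the simulated data the model recovered 25.4% of 2-fold and 78.8% of 4-fold changes for Diff minus ESC. It recovered 31.3% and 72.7% for Mid minus Diff, and 28.4% and 89.4% for Late minus Mid. The shares were 38.8% and 84.8% for nEnd minus XEN, 29.9% and 83.3% for NACL minus 2iL, 47.8% and 84.8% for ADE minus EpiSC, and 59.7% and 84.8% for nEnd minus ADE, and 0 were called in the wrong direction.

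Alternatives were another background correction (normexp with an offset of 50, on the median signal since the files hold no mean signal), quantile normalisation, median centring, no filter or a stricter filter, the mean of all probes of a gene, only the arrays compared, another prior, a 2-fold minimum, the series matrix, blocks for replicate number, cell line or slide, and leaving out each array. A block for scan day and a fit of the first scan day alone were added after the data were seen. NACL and 2iL arrays are paired by cell line. For the others, the deviations of same-numbered arrays from their group means were correlated; Late and Mid arrays each correlated best with their own number (0.218, 0.129 and 0.141), and Late arrays did so with ESC as well (0.252, 0.0837 and 0.125), from which Late also differs by its culture. Late minus Mid is therefore given with and without pairs, and whether the numbers mark pairs is not stated in the labels. Probes without a symbol entered no comparison and are counted apart.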

Results

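Messenger RNA levels were measured on 29 single-colour arrays in 9 groups, which the labels describe as stages of a conversion of naive pluripotent cells into expandable endoderm, with reference cultures. The first set of arrays holds ESC (3 arrays), Diff (3), Mid (3), Late (3) and XEN (3), and the second holds 2iL (3), EpiSC (3), ADE (4) and NACL (4). Between 49.2% and 79.7% of probes were well above background per array. Values are log2 signals relative to each array's 75th percentile, and changes are log2 differences with their standard error (SE) and limma's adjusted p over 16332 genes. Replicate arrays correlated at 0.939 or more within every group.

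**Figure D1:**
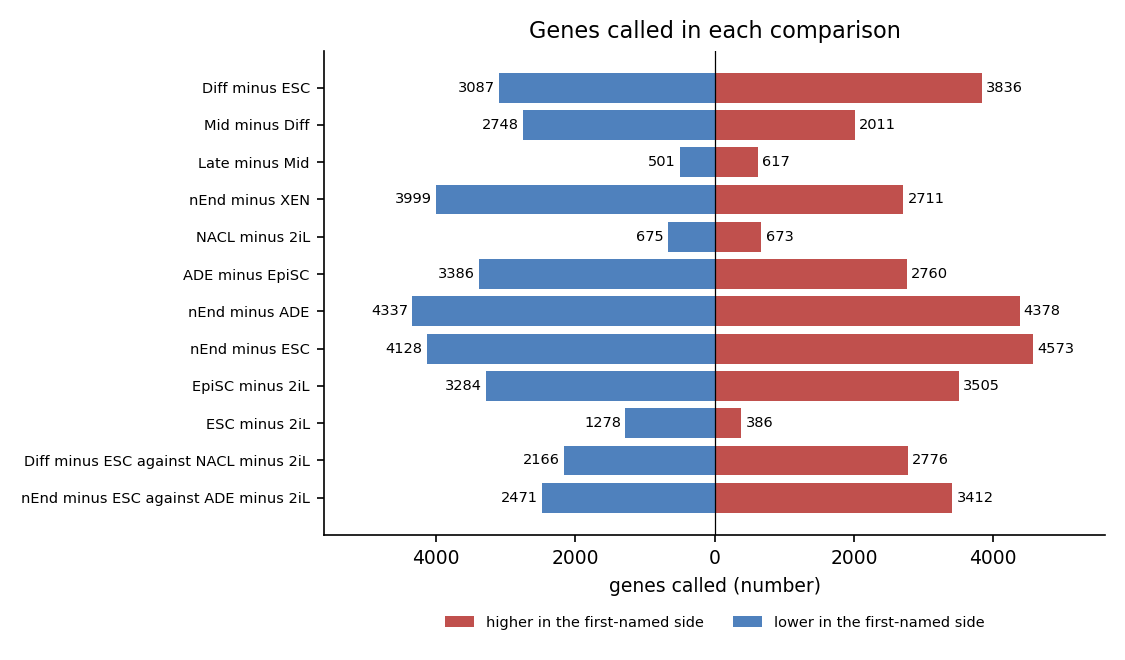
Number of genes called higher (right) and lower (left) in each comparison, at limma's adjusted p under 0.05 over 16332 genes. The counts run from 1118 for Late minus Mid to 8715 for nEnd minus ADE.

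Diff minus ESC asks what 7 to 8 days of Activin, CHIRON and LIF did to naive stem cells. The cells gained an endoderm programme: genes of basement membrane, of an endocytic apparatus for taking up nutrients, and transcription factors of primitive endoderm. Definitive endoderm genes rose as well, and no test set the extraembryonic lists against the definitive one. Part of the genes that hold stem cells in the naive state fell, though as a list they did not hold with an estimated correlation. Nanog and Sox2 were lower but still measured on all arrays. Single genes fell as well, among them Oas1a, which interferon induces, and Mt2, which binds metal. Some pluripotency-associated genes went the other way, among them Dnmt3l and Lin28a.

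Col4a2, a collagen chain of basement membranes, rose by 11.14 ± 0.54 (SE, n = 3 and 3; adjusted p = 4.6e-13), and Lamb1, a laminin chain, by 7.05 ± 0.42. Amn, part of the cubilin uptake receptor, rose by 9.63 ± 0.40, and Lrp2, the uptake receptor megalin, by 9.40 ± 0.48. Cubn and Dab2, a receptor and an adaptor of the same uptake route, were not well above background on the ESC arrays and were at least 3357-fold and 1549-fold higher in Diff. Gata6, a transcription factor that sets primitive endoderm identity, rose by 9.94 ± 0.61, with 1 of 3 ESC arrays well above background, and Sox7, a factor of early extraembryonic endoderm, was at least 220-fold higher. Nanog, a core naive factor, fell by 4.65 ± 0.77 (adjusted p = 3.3e-05), Nr5a2, a nuclear receptor of the naive state, fell by 4.64 ± 0.54, and Sox2 fell by 3.17 ± 0.74. Mt2, a metal-binding metallothionein, fell by 6.18 ± 0.50, and Oas1a, an interferon-induced enzyme, fell by 6.63 ± 0.71. Dnmt3l, a cofactor of DNA methylation, rose by 4.37 ± 0.60, and Lin28a, an RNA-binding protein of early embryos, by 3.61 ± 0.29. Zscan4c, a gene of early cleavage embryos, rose by 5.36 ± 0.96. The highest adjusted p among the genes named for this comparison was 0.0013, for Sox2.

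Across all genes 6923 were called, 3836 higher and 3087 lower, and 56.3% of genes had arrays without overlap, where chance gives 10%. Of 20 primitive endoderm genes 19 rose, and again 19 adjusted over the list alone (median 9.19, camera adjusted p = 6.7e-20). Visceral endoderm genes (17 of 21 rose, 17 adjusted over the list alone, adjusted p = 2.2e-10), basement membrane genes (15 of 19 rose, 15 adjusted over the list alone, adjusted p = 3e-07), definitive endoderm genes (14 of 21 rose, 14 adjusted over the list alone, adjusted p = 7.7e-08) and lipid transport genes (14 of 24 rose, 14 adjusted over the list alone, adjusted p = 6.3e-06) also moved up. These lists are not independent, since Sox17, Foxa2 and Gata6 sit in more than 1 of them, and all 5 held with an estimated correlation. Of 20 naive pluripotency genes 10 fell, 10 adjusted over the list alone (camera adjusted p = 0.0039; adjusted p = 0.25 with an estimated correlation). Of 29 lists 10 were called, 6 of them with an estimated correlation. Centring each array on its median instead raised the median of all genes by 0.361 and the share of called genes that were higher from 55.4% to 74.1%, so the balance of directions is tied to the scaling.

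**Figure D2:**
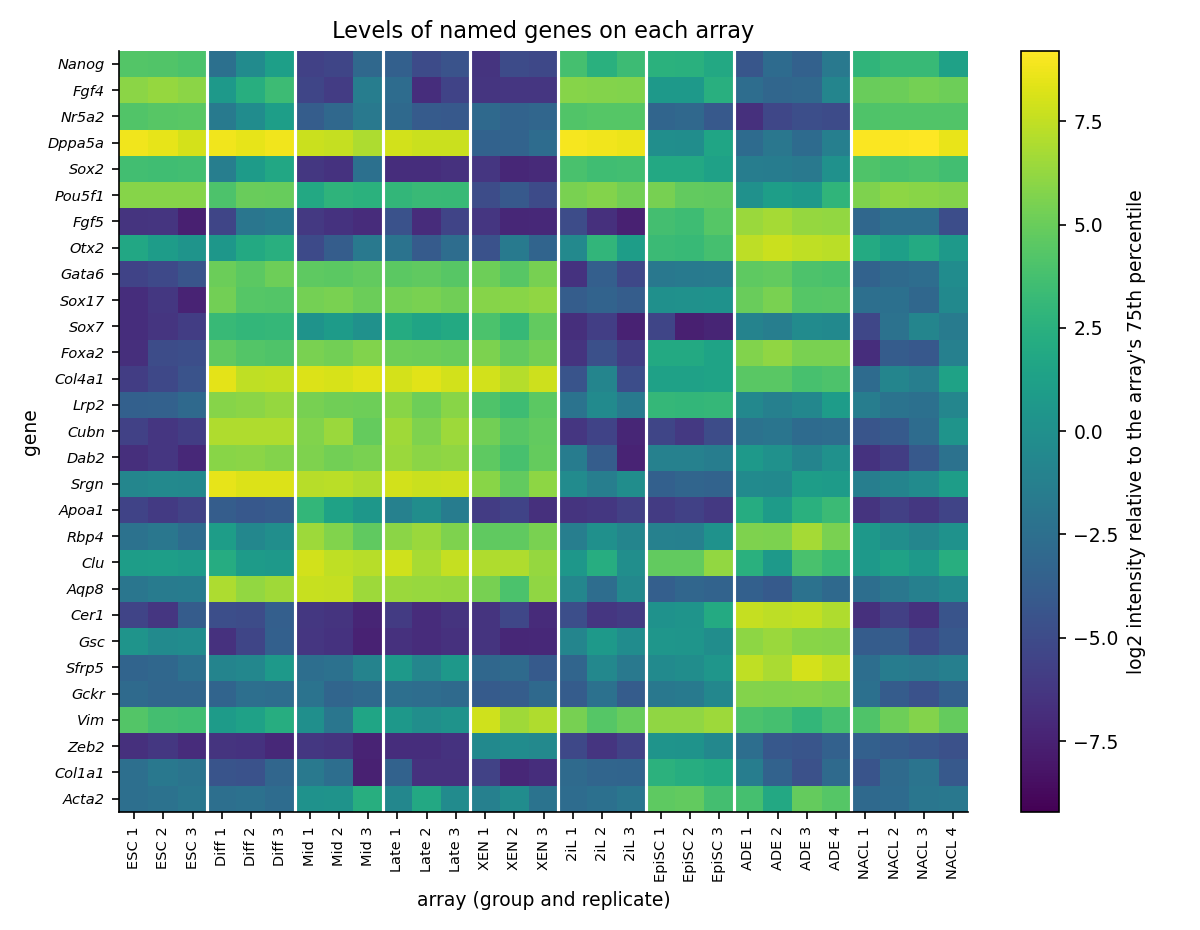
Log2 signal relative to the array's 75th percentile for marker genes, as colour, with 1 row per gene and 1 column per array. Gata6 and Sox17 are high in Diff, Mid, Late, XEN and ADE arrays and low in ESC arrays.

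Mid minus Diff asks what changed when the differentiated cultures were expanded to passage 7 to 10. Most naive pluripotency and cleavage-stage genes fell, as did some targets of Nodal signalling and most cell cycle genes. Some visceral endoderm genes rose, among them Rbp4 and Apoa1. Primitive endoderm genes as a list were not called in either direction.

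Dnmt3l fell by 6.66 ± 0.60 (SE, n = 3 and 3; adjusted p = 4.5e-08) after its rise in Diff. Sox2 fell by a further 5.49 ± 0.74 and Nanog by 4.17 ± 0.77, each well above background on 1 of 3 Mid arrays; another probe of Nanog was called in the opposite direction. Zscan4f and Zscan4c, of the same cleavage-stage family, fell by 6.92 ± 1.29 and 5.43 ± 0.96. Nodal, a signal of the TGF-beta family, fell by 4.24 ± 0.49, and Lefty2, its feedback inhibitor, fell by 4.68 ± 0.74. Rbp4, a carrier of retinol, rose by 5.58 ± 0.50, Apoa1, an apolipoprotein, by 5.61 ± 0.52, and Clu, a secreted chaperone, by 6.27 ± 0.65. Ghrl, which encodes the gut hormone ghrelin, rose by 7.06 ± 0.49. Gkn2 and Reg3g, secreted proteins of the gut lining, were at least 71.3-fold and 35.0-fold higher, from below background in Diff. Sox7 fell by 2.66 ± 0.75 and was the only 1 of 20 primitive endoderm genes called (median -0.15, camera adjusted p = 0.94). Its adjusted p of 0.0098 was the highest among the genes named.

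Across all genes 4759 were called, 2011 higher and 2748 lower, and 39.2% of genes had arrays without overlap, where chance gives 10%. Naive pluripotency genes (16 of 20 fell, 17 adjusted over the list alone, camera adjusted p = 1.1e-07; adjusted p = 0.14 with an estimated correlation) and germline and cleavage-stage genes (12 of 15 fell, 13 adjusted over the list alone, adjusted p = 1.1e-06; adjusted p = 0.14 with an estimated correlation) led the decreases, beside general pluripotency genes (10 of 15 fell, 11 adjusted over the list alone, adjusted p = 2.9e-06; adjusted p = 0.14 with an estimated correlation). Activin and Nodal target genes (7 of 15 fell, 7 adjusted over the list alone, adjusted p = 0.017; adjusted p = 0.44 with an estimated correlation) and, upwards, visceral endoderm genes (7 of 21 rose, 7 adjusted over the list alone, adjusted p = 0.04; adjusted p = 0.47 with an estimated correlation) were called less clearly. Cell cycle genes followed (15 of 21 fell, 17 adjusted over the list alone, median -0.83, adjusted p = 3.5e-06; adjusted p = 0.44 with an estimated correlation). Of 29 lists 11 were called, and 0 with an estimated correlation (camera; 11 of 29 at the preset one). The arrays differed by scan day within both groups, and a fit on the arrays of the first scan day alone, chosen after the data were seen, called 3372 genes. Median centring gave 2903, the arrays compared alone 2727 and replicate number as a block 1930.

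Late minus Mid asks whether the cultures kept changing between passage 7 to 10 and passage 14 to 15. Fewer genes changed than in the earlier steps. Without pairing, some cholesterol synthesis and cell cycle genes were higher in Late cultures and a few p53-linked growth arrest genes were lower. No endoderm list was called.

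Tcf15, a transcription factor linked to epiblast priming, rose by 3.16 ± 0.57 (SE, n = 3 and 3; adjusted p = 0.0018), and Tdh, a threonine-degrading enzyme of stem cells, by 3.07 ± 0.58. Pmaip1, a p53 target that promotes cell death, fell by 3.36 ± 0.38 (adjusted p = 1.7e-05), and Gdf15, a stress-induced secreted factor, fell by 3.63 ± 0.67. Cxcl5, a chemokine, was at least 8.62-fold lower, down to below background in Late. Nod1, a sensor of bacterial cell walls, rose by 3.24 ± 0.44. The highest adjusted p among these genes was 0.0024, for Tdh.

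Across all genes 1118 were called, 617 higher and 501 lower, and 29.5% of genes had arrays without overlap, where chance gives 10%. Cholesterol synthesis genes (5 of 20 rose, 9 adjusted over the list alone, camera adjusted p = 3.8e-05; adjusted p = 0.93 with an estimated correlation) and cell cycle genes (5 of 21 rose, 7 adjusted over the list alone, adjusted p = 0.00073; adjusted p = 0.99 with an estimated correlation) went up. The p53 and growth arrest genes went down (2 of 18 fell, 5 adjusted over the list alone, adjusted p = 0.00073; adjusted p = 0.34 with an estimated correlation), and these 3 were the only lists of 29 called. With replicates paired by number limma called 0 genes at an adjusted p under 0.05, 3488 at an unadjusted p under 0.05, so none of the genes named here kept its call; the 3 lists did, at camera adjusted p = 1e-05, 0.0061 and 0.0012. The median of all genes lay at 0.119, and with median centring it moved by -0.158 and 23.4% of called genes were higher in place of 55.2%. Leaving out Mid 1, Mid 2, Late 1 or Late 3 gave 499, 659, 438 or 409 genes, median centring 384 and the arrays compared alone 255. Mid 3 was read on the second scan day and all Late arrays on the first, and with scan day as a block, chosen after the data were seen, 703 were called.

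The distance of each culture from XEN cells, over all 16332 genes, asks whether passaging brings the cultures nearer to an established extraembryonic endoderm line. It was 2.15 ± 0.03 in ESC, 1.72 ± 0.07 in Diff, 1.49 ± 0.02 in Mid and 1.44 ± 0.01 in Late (mean and SD, n = 3 each). Single XEN arrays lay 0.735 ± 0.021 from the mean of the other XEN arrays. That reference differs from the mean of all XEN arrays used for the cultures. Every Late array lay nearer than every Mid array and every Mid array nearer than every Diff array. The gap between Late and Mid was narrow, from 1.453 (Late 1) to 1.47 (Mid 2). Mid 3, the farthest Mid array, was read on the second scan day and all Late arrays on the first. No alternative for the distances took slide or scan day into account. Each of the 3 exact permutation tests gave p = 0.1 (adjusted p = 0.1), the smallest that 3 against 3 arrays can give. The test of Late against Mid left pairing by number aside, and 3 pairs would allow only a larger p.

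**Figure D3:**
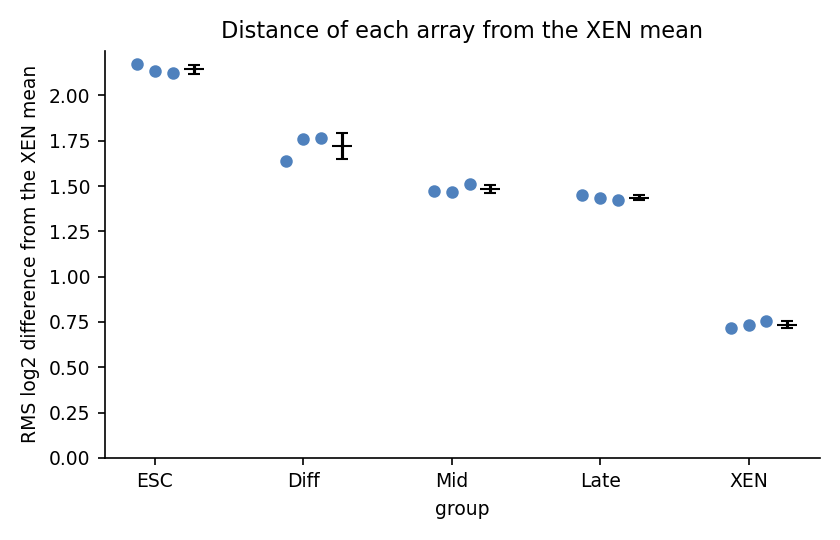
Root mean square log2 difference of each array from the mean of the XEN arrays over all genes tested, 1 point per array with the group mean and SD. Each XEN array was set against the mean of the other XEN arrays. The means fall from 2.15 in ESC to 1.44 in Late.

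The comparison nEnd minus XEN asks how passaged endoderm differs from XEN cells, a line of parietal-like character. Both had high Gata6 and Sox17. Some lipid transport and visceral endoderm genes were higher in nEnd, among them apolipoproteins and uptake receptors, as was the tight junction gene Cldn7. The lipid transport list held with an estimated correlation, and the visceral endoderm list did not. XEN cells were higher in Vim, in Zeb2 and in most cell cycle genes. Passaged nEnd still carried transcripts of some pluripotency genes that were low in XEN cells.

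Dppa5a, an RNA-binding protein of the naive state, was higher by 10.74 ± 0.35 (SE, n = 6 and 3; adjusted p = 1e-16), and Dppa2, a chromatin factor of early embryos, by 4.64 ± 0.66. Pou5f1, the pluripotency factor Oct4, was higher by 7.47 ± 0.38, with 1 of 3 XEN arrays well above background. Cldn7, a tight junction protein, was higher by 8.26 ± 0.52, while Vim, an intermediate filament of mesenchymal cells, fell by 7.11 ± 0.51 and Zeb2, a repressor of epithelial genes, was at least 17.8-fold lower. Amn was higher by 5.16 ± 0.35, Apom, an apolipoprotein, by 4.41 ± 0.30, and Apoa1 at least 32.7-fold. Stra6, a retinol receptor, fell by 3.78 ± 0.66 and Fst, an inhibitor of Activin, fell by 3.00 ± 0.57. Rrm2, which supplies nucleotides for replication, fell by 2.38 ± 0.34 and Mcm3, a replication helicase subunit, fell by 1.63 ± 0.18. The highest adjusted p among these genes was 0.00018, for Fst. The 6 nEnd arrays were taken as independent here and in nEnd minus ADE and nEnd minus ESC. If Mid and Late arrays of the same number are pairs, these SE and p-values may be too small.

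Across all genes 6710 were called, 2711 higher and 3999 lower in nEnd, and 30.7% had arrays without overlap, where chance gives 2.38%. Lipid transport genes (13 of 24 higher, 13 adjusted over the list alone, camera adjusted p = 0.00011) held with an estimated correlation, alone among the 5 lists called of 29. Visceral endoderm genes (12 of 21 higher, 12 adjusted over the list alone, adjusted p = 1.3e-05; adjusted p = 0.14 with an estimated correlation), naive pluripotency genes (9 of 20 higher, 10 adjusted over the list alone, adjusted p = 0.00014; adjusted p = 0.25 with an estimated correlation) and cell cycle genes (18 of 21 lower, 18 adjusted over the list alone, adjusted p = 2.1e-07; adjusted p = 0.46 with an estimated correlation) followed. Primitive endoderm genes split, with 4 higher and 4 lower of 20 (adjusted p = 0.92), and genes of the epithelial to mesenchymal transition were not called as a list (8 higher and 4 lower of 18, 8 and 5 adjusted over the list alone, adjusted p = 0.21). The line differs between both sides, so line and culture cannot be separated. The share of called genes that were higher moved from 40.4% to 24% with median centring, which shifted the median of all genes by -0.355.

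NACL minus 2iL asks how stem cells in stable culture differ between Activin, CHIRON and LIF and 2i with LIF. Both media hold LIF and 2i is absent from NACL by its label, so the effect of Activin alone was not tested. Some targets of FGF and ERK signalling, which an inhibitor in 2i blocks, and a few early epiblast genes were higher, though neither list held with an estimated correlation. The naive network as a list was not called. A few primitive endoderm genes were higher from a low base.

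Dusp6 and Dusp4, feedback phosphatases of ERK, rose by 2.89 ± 0.27 (SE, n = 4 and 3; adjusted p = 1.1e-06) and 3.55 ± 0.45, and Spry4, a feedback inhibitor of the same route, was at least 27.0-fold higher. Tcf15 rose by 2.87 ± 0.53 and Crmp1, a protein of growing axons, by 3.42 ± 0.58. Ly6c1, a membrane antigen, fell by 5.82 ± 0.66 and Tlx2, a homeobox gene, fell by 5.58 ± 0.45, as did Rhox2c, a reproductive homeobox gene, by 5.12 ± 0.51. Bhmt, an enzyme of methionine metabolism, fell by 4.96 ± 0.69. Gata6 was higher by 2.82 ± 0.57 (adjusted p = 0.0025; by 2.15 without NACL 4) and Sox7 at least 4.57-fold, on 4 and 3 of 4 NACL arrays well above background (Gata6 also on 1 of 3 2iL arrays), and both lost their call with cell line as a block. No gene named here had a higher adjusted p than Gata6. Of 20 primitive endoderm genes 6 were higher and 1 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.16).

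Across all genes 1348 were called, 673 higher and 675 lower, and 15.5% had arrays without overlap, where chance gives 5.71%. FGF and ERK target genes (8 of 18 rose, 10 adjusted over the list alone, camera adjusted p = 3.6e-07; adjusted p = 0.089 with an estimated correlation) and primed epiblast genes (4 of 20 rose, 4 adjusted over the list alone, adjusted p = 0.013; adjusted p = 0.52 with an estimated correlation) were the 2 lists called of 29, the second not without 2iL 2 (adjusted p = 0.069). Of 20 naive pluripotency genes 1 was called (adjusted p = 0.64). Both groups hold the same 3 lines, and with line as a block 248 genes were called and both lists kept their call. Leaving out 2iL 1 gave 819 genes.

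ADE minus EpiSC asks how epiblast stem cells change over 4 days on the way to anterior definitive endoderm. Definitive and anterior visceral endoderm genes came up as lists, together with visceral endoderm genes and, less clearly, primitive endoderm genes. These lists are not independent, since Cer1, Hhex, Otx2 and Foxa2 sit in both the definitive and the anterior visceral list. No test told anterior visceral from definitive endoderm. Nanog, Pou5f1 and part of the fibroblast genes fell, as did most glycolysis and cell cycle genes.

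Cer1, a secreted inhibitor of Nodal, BMP and Wnt, rose by 6.54 ± 0.59 (SE, n = 4 and 3; adjusted p = 1.3e-08), Hhex, a homeobox factor of anterior endoderm, by 6.05 ± 0.38, Gsc, an organiser factor, by 5.86 ± 0.48, and Sfrp5, a Wnt inhibitor, by 7.49 ± 0.53. Gata6 rose by 6.05 ± 0.57, Gata4, its relative, by 6.01 ± 0.38, and Sox17, an endoderm factor, by 4.71 ± 0.41. Apoa1 was at least 145-fold higher. Nanog fell by 5.39 ± 0.72 and Pou5f1 by 3.79 ± 0.41. T, the primitive streak factor brachyury, fell by 4.08 ± 0.93, with 3 of 4 ADE arrays well above background, and Col1a1, a fibrillar collagen, fell by 5.35 ± 0.99. Nr0b1, a nuclear receptor counted as naive, went the other way and was at least 322-fold higher. Aldoc, a glycolytic aldolase, fell by 3.63 ± 0.58 and Ccnb2, a mitotic cyclin, fell by 1.76 ± 0.17. The highest adjusted p among the genes named was 0.0012, for T.

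Across all genes 6146 were called, 2760 higher and 3386 lower, and 47.7% had arrays without overlap, where chance gives 5.71%. Definitive endoderm genes (18 of 21 rose, 19 adjusted over the list alone, camera adjusted p = 5.3e-13), anterior visceral endoderm genes (11 of 12 rose, 11 adjusted over the list alone, adjusted p = 7.4e-13) and visceral endoderm genes (15 of 21 rose, 16 adjusted over the list alone, adjusted p = 1.3e-08) held with an estimated correlation, 3 of 10 lists called. Primitive endoderm genes (13 of 20 rose, 13 adjusted over the list alone, adjusted p = 1.5e-05; adjusted p = 0.2 with an estimated correlation) and genes of mesendoderm and primitive streak (6 of 16 rose and 2 fell, 7 and 2 adjusted over the list alone, adjusted p = 0.046; adjusted p = 0.42 with an estimated correlation) were also called. Cell cycle genes (16 of 21 fell, 16 adjusted over the list alone, adjusted p = 2.3e-06; adjusted p = 0.42 with an estimated correlation), glycolysis genes (14 of 21 fell, 15 adjusted over the list alone, adjusted p = 0.00014; adjusted p = 0.42 with an estimated correlation) and fibroblast genes (7 of 13 fell, 8 adjusted over the list alone, adjusted p = 0.0035; adjusted p = 0.19 with an estimated correlation) went down. General pluripotency genes were called lower (7 of 15 fell, 9 adjusted over the list alone, adjusted p = 0.034; adjusted p = 0.47 with an estimated correlation), and naive pluripotency genes were not called (4 rose and 10 fell of 20, 4 and 10 adjusted over the list alone, adjusted p = 0.087).

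The comparison nEnd minus ADE sets the passaged endoderm beside endoderm made from the later, primed state. Both held Gata6 and Sox17, but nEnd had higher levels of most basement membrane, lipid transport and primitive endoderm genes and most targets of LIF. ADE was higher in most anterior visceral endoderm genes, most primed epiblast genes and most targets of Nodal. These lists share members, such as Otx2, Cer1 and Gsc, and no test told anterior visceral from definitive endoderm. Both sides come from different array sets, so set and cell type cannot be separated in the direct difference.

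Lama1, a laminin chain of early basement membranes, was higher by 8.54 ± 0.28 (SE, n = 6 and 4; adjusted p = 1.9e-16), Plod2, which modifies collagen, by 6.43 ± 0.24 and Cubn by 8.39 ± 0.59. Dppa5a was higher by 9.76 ± 0.32, Klf4, a naive factor and LIF target, by 5.97 ± 0.22, and Socs3, a feedback inhibitor of LIF signalling, by 4.94 ± 0.33. Cer1, Gsc and Fgf5, a growth factor of primed epiblast, were at least 3958-fold, 1596-fold and 2023-fold lower, below background in nEnd. Otx2, a factor of anterior and primed cells, fell by 10.69 ± 0.64, with 5 of 6 nEnd arrays well above background, and Nodal fell by 6.54 ± 0.39. Eif2s3y, a gene on the Y chromosome, was at least 244-fold higher, from below background in ADE, although its level also varied by 2.45 over the ESC arrays. The highest adjusted p among these genes was 2.9e-11, for Cubn.

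Across all genes 8715 were called, 4378 higher and 4337 lower, and 40.8% had arrays without overlap, where chance gives 0.952%. The anterior visceral endoderm genes (10 of 12 lower, 11 adjusted over the list alone, camera adjusted p = 6.1e-10), primed epiblast genes (13 of 20 lower, 13 adjusted over the list alone, adjusted p = 1.8e-06), basement membrane genes (15 of 19 higher, 15 adjusted over the list alone, adjusted p = 1.2e-05), LIF and STAT3 target genes (14 of 18 higher, 14 adjusted over the list alone, adjusted p = 4.2e-05) and lipid transport genes (15 of 24 higher, 15 adjusted over the list alone, adjusted p = 0.00038) held with an estimated correlation, 5 of 16 lists called. Primitive endoderm genes (16 of 20 higher, 16 adjusted over the list alone, adjusted p = 8e-07; adjusted p = 0.075 with an estimated correlation) and Activin and Nodal target genes (12 of 15 lower, 12 adjusted over the list alone, adjusted p = 5.5e-06; adjusted p = 0.062 with an estimated correlation) followed. With each side referred to the 2i and LIF cells of its own array set, which for ADE are other lines than its own, so that line is mixed in, the difference called 5883 genes, with anterior visceral endoderm (adjusted p = 7.5e-12), basement membrane (adjusted p = 9.5e-05) and LIF target genes (adjusted p = 0.00015) called in the same direction, the first also with an estimated correlation (adjusted p = 0.0031), the only 1 of 14 lists called there for which this held; primed epiblast (adjusted p = 0.075 with an estimated correlation), basement membrane, LIF target and lipid transport genes (adjusted p = 0.069 with an estimated correlation for each) lost it. With nEnd as 1 group it called 5541, and of 100 regroupings of the arrays 3 gave as many, the real one included. There Dppa5a differed by 10.14 ± 0.52, with changes of -0.85 in nEnd and -10.99 in ADE, and Fgf8, a growth factor of the streak, by -7.82 ± 0.59, with changes of -0.27 and 7.55.

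**Figure D4:**
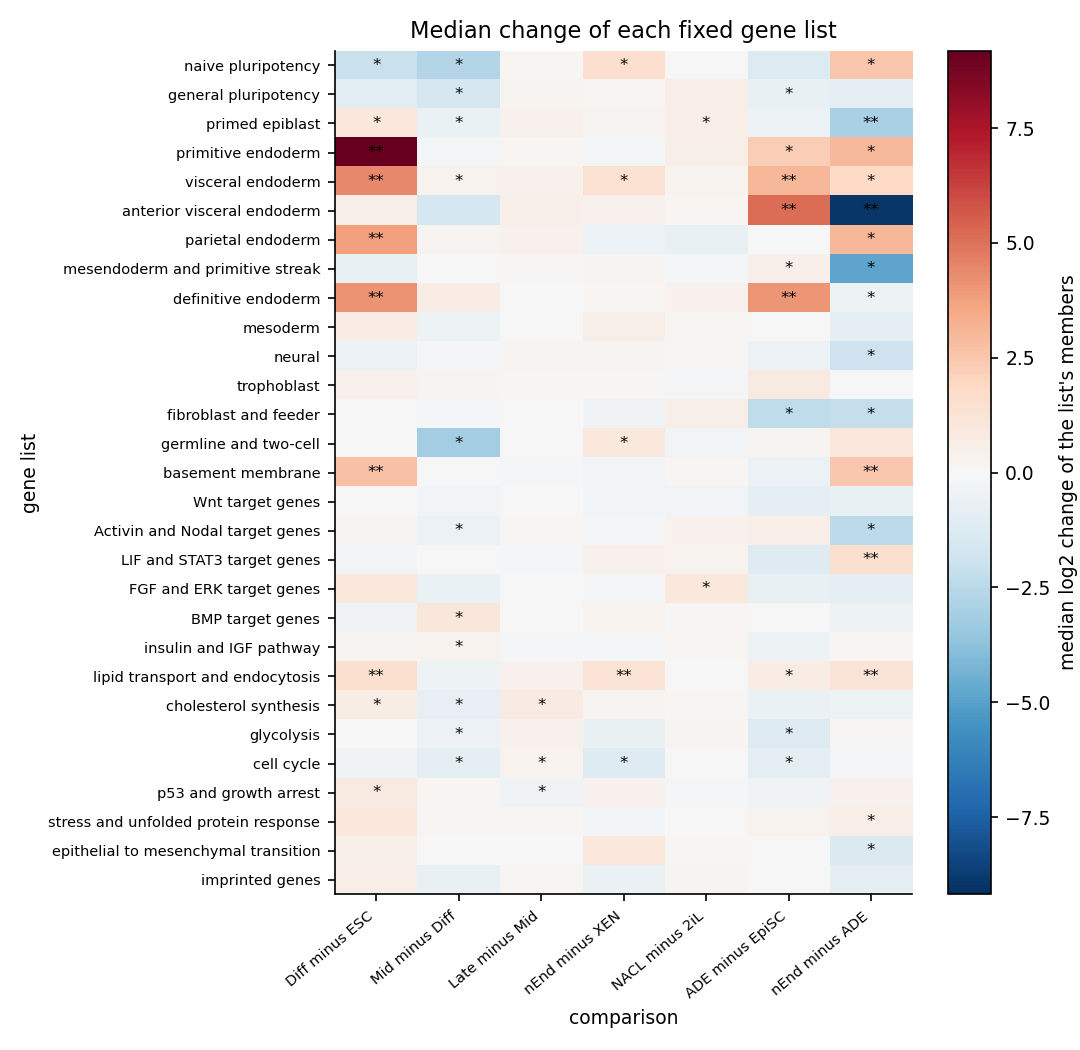
Median log2 change of the 29 gene lists in each main comparison, as colour, with 1 mark where camera's adjusted p was under 0.05 and a pair of marks where it was also under it with an estimated correlation. Primitive endoderm genes rise in Diff minus ESC (median 9.19) and barely move in Mid minus Diff (median -0.15).

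Secondary comparisons set the reference cultures apart. In nEnd minus ESC, 8701 genes were called, 4573 higher and 4128 lower, and all 20 primitive endoderm genes rose (20 adjusted over the list alone, camera adjusted p = 2.6e-16, held with an estimated correlation). Spink1, a trypsin inhibitor of visceral endoderm, rose by 10.51 ± 0.52 (SE, n = 6 and 3), and Nr5a2 fell by 7.61 ± 0.46. Median centring moved the median of all genes by 0.285 and the share higher from 52.6% to 66.3%. In EpiSC minus 2iL, where the lines differ with the state, 6789 genes were called, 3505 higher and 3284 lower, and naive pluripotency genes fell (18 of 20, 18 adjusted over the list alone, adjusted p = 2.5e-17) while primed epiblast genes rose (15 of 20, 16 adjusted over the list alone, adjusted p = 5.8e-08), both held with an estimated correlation. Tdh fell by 10.52 ± 0.58 and Fgf5 was at least 370-fold higher. In ESC minus 2iL, the same medium in other lines on other array sets, 1664 genes were called, 386 higher and 1278 lower. Snrpn, an imprinted gene, fell by 6.15 ± 1.29 (adjusted p = 0.0047), though it also ranged over 4.42 among the Diff arrays, and Stra8, a gene of germ cells entering meiosis, fell by 3.96 ± 0.81 there. The share higher of 23.2% became 4.83% with median centring and 42.4% with the series matrix, so set, line and scaling all bear on it. Leaving out ESC 1, ESC 2, ESC 3 or 2iL 2 gave 857, 837, 995 or 889 genes. Median centring gave 1015, the arrays compared alone 569 and replicate number as a block 0, although equal numbers join different lines here.

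The difference of Diff minus ESC from NACL minus 2iL compares a differentiating with a stable culture. It asks whether the step from 2i with LIF to Activin, CHIRON and LIF went with different changes. It called 4942 genes, 2776 higher and 2166 lower, and all 20 primitive endoderm genes were higher (20 adjusted over the list alone, camera adjusted p = 1.3e-22, held with an estimated correlation). Col4a2 differed by 9.96 ± 0.75 and Lrp2 by 9.65 ± 0.66. Median centring moved the share higher from 56.2% to 79.3% and the median of all genes by 0.386. Each change was taken within its own array set, but the lines differ, and 9 of 100 regroupings of the arrays, the real one included, gave a count as large.

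Deviations of arrays from their group means, correlated across genes between arrays of different groups, averaged 0.127 on the same slide and -0.123 on different slides in the second array set, and 0.044 and -0.0191 in the first, so slides left a trace, more so in the second set. With slide as a block the counts were 6653 for Diff minus ESC, 4744 for Mid minus Diff, 1640 for Late minus Mid, 6496 for nEnd minus XEN, 1614 for NACL minus 2iL and 6755 for ADE minus EpiSC; nEnd and ADE share no slide, nor do ESC and 2iL, so slide cannot be separated from the groups there.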

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

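The tests of Y-linked genes, of endoderm genes in NACL and of Snrpn, and the fit with scan day as a block, were chosen only after the results were seen, while the splits of the arrays were planned.

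Genes on the Y chromosome were dim in EpiSC, ADE and XEN, near -7 for Eif2s3y, Ddx3y and Uty alike, and uneven between ESC and Diff arrays, although the labels call every culture male. Array brightness or scaling is argued against, since the X-linked twin Eif2s3x changed by -0.25 from 2iL to EpiSC, while Eif2s3y went from 3.68 to a level near background. A shift with culture state cannot account for the spread of Eif2s3y among ESC arrays in the same medium (2.45), but this says nothing of EpiSC, ADE and XEN, where it stays open. Loss of the chromosome in a share of the cells may explain the ESC and Diff arrays, where the deficits of the 3 genes from 2iL differed within an array by 0.794 on average, from 0.397 (ESC 2) to 1.47 (ESC 3), with Uty near its lowest level on ESC 3 and Diff 3, so that its deficit there is only a bound. It leaves open Mid, where Ddx3y ran from -2.24 to 1.17 while Eif2s3y held between 2.82 and 3.47, and a wrong sex label was not tested. Xist, which bears on sex, lay between -7.33 and -6.25 in EpiSC, ADE and XEN. It ran from -5.04 to -1.99 in Mid and from -2.92 to -1.81 in Late, and no conclusion on sex was drawn from it.

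Endoderm genes were higher in NACL than in 2iL from a low base, with 6 of 20 primitive endoderm genes called higher. A single NACL array is argued against, since 5 of those 6 stayed called without NACL 4; Col4a1 did not (adjusted p = 0.11), and with cell line as a block Gata6 (adjusted p = 0.12), Sox7, Sox17, Cubn and Col4a1 lost their call, Gata6 at a change of 3.13 ± 0.71 in place of 2.82 ± 0.57. A small share of cells like the Diff cultures could not be excluded: the share read from Gata6 and Sox17 was 0.264%, 0.363%, 0.261% and 2.49% on the 4 arrays. The share read from 50 transcripts abundant in Diff, of which 19 sit in endoderm lists, was -0.0187%, 0.18%, 0.0469% and 1.14%, a median gap of 1.8 on the log2 scale. A low uniform expression in all cells stays open beside it and was not tested.

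Snrpn was lower in ESC than in 2iL (by 6.15), the largest decrease among the genes that the naming rule picks there. A difference between the 2 sets of arrays is argued against, since within the second set Snrpn changed by -6.79 from 2iL to EpiSC. A fixed difference between lines stays open, since spread within 1 line cannot exclude an offset between lines. Within HRHnG, Diff arrays ranged over 4.42 and 3 of 19 arrays lay within 2 of the lowest 2iL array. Yet the highest HRHnG array (0.792) still lay below that array (difference -0.643). All 2iL arrays (1.44 to 3.31) and all NACL arrays, which are of the same lines as 2iL (2.78 to 3.21), lay above every HRHnG array. A loss or gain of imprinting that varies between cultures is a candidate explanation that was not tested.

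The 2 differences of differences were tested directly. The change from ESC to Diff differed from that of 2iL to NACL for 4942 genes, and chance is not excluded, since 9 of 100 regroupings, the real one included, gave as many (highest other 5963). All 9 were among the 17 that kept or mirrored Diff against ESC whole, and the regroupings that did not called at most 14. The change from ESC to nEnd differed from that of 2iL to ADE for 5883 genes; with nEnd as 1 group of 6 arrays the count was 5541, and 3 of 100 regroupings, the real one included, gave as many (highest other 7202). The others kept ADE against 2iL whole. In both cases a large count needs only 1 contrast kept whole, so the share follows how often a draw does that and does not exclude chance.

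Splits of the arrays into other groups of the same sizes gave fewer genes than the real one in every comparison of 2 groups. For ADE minus EpiSC (1 of 35 splits as large; 6146, highest other 3667) chance is excluded only if slide is left aside, since splits within slides are too few for a share under 0.05, and with slide as a block 6755 genes were called. With nEnd as 1 group and its 6 arrays taken as independent, slide again left aside, chance is excluded for nEnd minus XEN (1 of 84; 6414, highest other 2453 with Late and XEN against Mid), nEnd minus ESC (1 of 84; 8463, highest other 2285 with Late and ESC against Mid) and nEnd minus ADE (1 of 100; 8440, highest other 4991). Late and Mid arrays correlated best with their own number, so that independence is in doubt. If Mid and Late arrays of the same number are pairs, nEnd minus XEN and nEnd minus ESC have only 10 splits, too few for a share under 0.05, and for nEnd minus ADE such splits were not counted. The sides of nEnd minus ADE also come from different array sets, so its count cannot part cell type from set. For NACL minus 2iL (1 of 35; 1348, highest other 1182) chance is excluded only if cell line is left aside, since splits within lines are too few, and with line as a block 248 genes were called. In NACL and ADE the highest other split set array 4 with the other group, so it kept most of the real contrast. For groups of 3 and 3 the 10 splits are too few for a share under 0.05: Diff minus ESC gave 6923 and at most 3 otherwise, Mid minus Diff 4759 and 973, Late minus Mid 1118 and 8, EpiSC minus 2iL 6789 and 41, ESC minus 2iL 1664 and 4, with 1 split as large in each, the real one. The 973 came from Mid 1, Mid 2 and Diff 1 against Mid 3, Diff 2 and Diff 3, which differ from a split by scan day only in Diff 2; with scan day as a block Mid minus Diff called 4484. Of the 4 splits of Late and Mid that part all pairs, the others called 0.

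Single arrays were screened only in ADE and NACL, which hold 4 arrays each, and not in the groups of 3. They stood apart in 10 of 182 groups of values, 5.49% where chance gives 5%. The ratio of the gap to the range was 0.878 for the mean of Activin and Nodal target genes (ADE 2), 0.867 for B4galnt2 (ADE 1), 0.939 for Pfkp (ADE 4), 0.873 for Postn (ADE 1), 0.915 for Rbp4 (ADE 3) and 0.881 for Thbd (ADE 2). In NACL it was 0.886 for the median processed signal (NACL 4, 39.8 against at most 15.9), 0.83 for the mean of visceral endoderm genes and 0.911 for that of lipid transport genes (NACL 4 in both), and 0.902 for Sox11 (NACL 3).

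Probes without a gene symbol also changed. Of 15314 such probes tested, 3238 were called in Diff minus ESC, 2061 in Mid minus Diff, 82 in Late minus Mid, 2887 in nEnd minus XEN, 186 in NACL minus 2iL, 2011 in ADE minus EpiSC and 3949 in nEnd minus ADE.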

How the results depend on the processing

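The fits with scan day as a block and on the first scan day alone were chosen after the data were seen. Of 257 counts of called genes under alternatives, 226 stayed within 1.5 times the main count. All 45 distances to XEN kept their direction, and 0 of the distances, lists and named genes reversed. Part of this was fixed in advance. Fitting only the arrays compared, another prior or a 2-fold minimum leaves each gene's difference unchanged, and many named genes were picked for large changes. Up to 14 other called genes of a comparison were called in the opposite direction (nEnd minus ADE with the mean of all probes). Of 2244 tests of called lists 208 lost their call, and of 7131 values of named genes 230 did. Many of these tests left out only 1 array, and the losses were uneven between alternatives. With an estimated correlation 74 of 108 called lists lost their call, and on probes above background on all arrays 37 did. With replicate number as a block 62 of 352 values of named genes lost theirs. With cell line as a block 10 named genes of NACL minus 2iL did. Where counts moved, the cause was not tested, except that a 2-fold minimum only removes genes and a model on fewer arrays has a less certain spread. Median centring gave 2903 genes for Mid minus Diff, 384 for Late minus Mid, 849 for NACL minus 2iL and 1015 for ESC minus 2iL. Fitting only the arrays compared gave 2727, 255, 450 and 569 in that order. A 2-fold minimum gave 3077 for Mid minus Diff, 624 for Late minus Mid, 3886 for nEnd minus XEN, 3971 for ADE minus EpiSC, 5365 for nEnd minus ADE and 935 for ESC minus 2iL. With replicate number as a block, limma called 1930 for Mid minus Diff, 0 for Late minus Mid (3488 at an unadjusted p under 0.05), 319 for NACL minus 2iL and 0 for ESC minus 2iL (3671); it moved no other count beyond 1.5 times (5922 for Diff minus ESC, 5475 for nEnd minus XEN, 5328 for ADE minus EpiSC, 7898 for nEnd minus ADE, 9228 for nEnd minus ESC, 5071 for EpiSC minus 2iL, and 4314 and 5785 for the differences of differences). The labels do not say whether equal numbers mark pairs, and outside Late minus Mid not every array of a comparison correlated best with its own number. In NACL minus 2iL the numbers 2 and 3 join different lines, and ESC and 2iL share no line. The block by number therefore does not pair arrays by line in these comparisons. With cell line as a block NACL minus 2iL called 248, with scan day as a block Late minus Mid called 703, with slide as a random effect ESC minus 2iL called 1015, and on probes above background on all arrays NACL minus 2iL called 805 of fewer genes tested. Leaving out 1 array gave 409 (without Late 3) to 1272 (without Mid 3) for Late minus Mid, 819 (without 2iL 1) to 1661 (without NACL 4) for NACL minus 2iL, and 837 (without ESC 2) to 1474 (without 2iL 3) for ESC minus 2iL. Array signal over background limits all of these, since a gene dim on 1 side has only a bound there.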

Other observations

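No test in this part was chosen after its result was seen. No arrays were copies of each other: over 406 pairs of arrays at most 0.00359% of probes had identical values, and the highest correlation was 0.9836.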
